A study of Solanum tuberosum with 12 samples.

How the data were processed

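RNA from the upper 5 leaves of potato cultivar Desiree was converted to strand-specific libraries, in which oligo(dT) beads select poly(A) RNA and the dUTP-marked second strand is digested, per the labels' protocols. The plants stood in soil under 12 h of light and 12 h of darkness at NT (22 °C and 16 °C) or HT (35 °C and 29 °C) for 3 or 8 weeks, with 3 libraries in each of the 4 groups. Groups and replicate numbers were taken from the sample titles. The aligner, the counting program, their versions and the genome build are not given in the sources used here.

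The deposited files were 3 tables of the authors' comparisons of HT with NT, at 3 weeks, at 8 weeks, and for the 580 transcripts found in both, and the third repeated the counts of the others without a difference. Each transcript has a PGSC0003 identifier and a product name, per the file headers. None of the identifiers matched the reference gene table, so the product names of the files were used as they stand, with no chromosome positions. The authors' deposited raw counts per transcript and library were used for every test. The authors' group means are plain means of the 3 counts, a signal that was not tested. The deposited maximum group mean is an RPKM value, which sets reads against transcript length and library total. The authors' log2 fold changes, their signed fold change (a score that is the ratio HT to NT, or minus the inverse ratio), p-values, false discovery adjusted p-values and Bonferroni values were deposited with no test or tool named in the headers.

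The tables are selections. All listed transcripts had an absolute log2 fold change of at least 1.5 and a p-value under 0.01 in the authors' deposited tables. The ratio of Bonferroni value to p-value gave the number of the authors' tests, 33777 at 3 weeks and 34088 at 8 weeks. The adjusted p-values give the rank of a listed transcript among all those tests: 1445 of the first 7816 at 3 weeks (18.5%) and 5571 of the first 8403 at 8 weeks (66.3%) were listed. Products of unknown function made up 30.3% of the list at 3 weeks and 23.3% at 8 weeks.

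Listed counts are only 1.76% to 2.61% of a library at 3 weeks and 16.2% to 23.1% at 8 weeks, so their sums are not library sizes. The total of each library was solved from the deposited RPKM values, counts and transcript lengths, and lay between 52514661 and 66602938 counts. The authors' fold changes departed from those of counts over these totals by a constant 0.402 on the log2 scale at 3 weeks (1.321-fold) and by 0.095 at 8 weeks (1.068-fold), and this shift was applied between the HT and NT totals as the scaling of the tests of HT against NT. TMM was planned for full tables only; the plan ruled out estimating library sizes from a list of called transcripts, so TMM was not part of the main test. Comparisons between ages within a temperature used the library totals without a shift. A group with no counts was given 3 counts over its libraries as the floor for fold changes written as at least so many fold.

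Tests were run with edgeR 4.0.16 (quasi-likelihood F test, filterByExpr, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3 over the listed transcripts alone. The difference between ages was the interaction term over all 12 libraries, on the totals with the shift. Standard errors are the absolute log2 change over the root of F. CPM values are counts over the scaled totals. A set of 28 gene lists (heat response, photosynthesis, hormones, defence, cell wall, cell division and others) was fixed as search patterns on product names before the data were examined. For each list with at least 5 calls, Fisher's exact test, two-sided, compared higher and lower calls of members with those of all other calls, adjusted over the lists of an age, 17 at 3 weeks and 24 at 8 weeks. Lists with at least 5 calls at both ages were also compared between ages. These and the other Fisher's exact tests take transcripts as independent. Members of a list may vary together between libraries, so the p-values may be too small. Tables were handled with Python 3 packages pandas, numpy and SciPy.

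Genes were named by a rule fixed before the data were examined: of calls with the 3 HT libraries on one side of the 3 NT libraries and a mean of at least 10 counts in the higher group, the 6 largest rises and the 6 largest falls with a product name other than unknown, and up to 3 members of each list with at least 5 calls. Named without these conditions were the 5 shared transcripts with opposite directions and the largest smaller change, and all genes of the FT/TFL1 family and the circadian clock. Genes outside the rule are said to have been chosen after their values were seen.

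The tests were tried on simulated counts with 200 changed transcripts. On the 1304 transcripts of the 3-week simulation 71.9% of 2-fold changes and 100% of 4-fold changes were recovered, with 4.4% false calls. On the 5364 of the 8-week simulation the values were 67.1%, 100% and 5.6%, and for the interaction on 574 transcripts 96% of 4-fold differences, with 1.6% false calls. All other simulated transcripts were left unchanged, whereas the real lists hold only transcripts chosen as changed. The shares of false calls therefore do not carry over to the real calls. In 200 draws of the list test, with the direction of each transcript drawn independently, a planted list was found in 98.5% at 3 weeks and 100% at 8 weeks, and other lists in 0.34% and 0.28%. These draws do not cover members that vary together. No pair of replicates agreed within sampling noise (chi-square per degree of freedom 31.4 to 757), so none were merged.

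Alternatives tried were a replicate block, DESeq2 1.42.0 size factors from the listed transcripts, the DESeq2 Wald test, no filter on low counts, a 2-fold threshold, an adjusted p threshold of 0.01 and leaving out each library. Chosen after seeing the data were TMM factors from the list, library totals alone, adjustment over all tests of the authors, and, for the age comparisons, DESeq2 size factors and left-out libraries, as well as all changes of fit for the lists. The pseudocount and the rescaling planned for normalized values did not apply to counts.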

Results

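Leaf transcriptomes of potato (Solanum tuberosum) cultivar Desiree were measured in plants kept in soil for 3 or 8 weeks at normal temperature (NT, 22 °C in the light and 16 °C in the dark) or at high temperature (HT, 35 °C in the light and 29 °C in the dark). The upper 5 leaves were taken, and poly(A) RNA was sequenced from strand-specific libraries. Each of the 4 groups held 3 libraries, 12 in all, and the library totals recovered from the deposited values ran from 52514661 to 66602938 counts. The deposited tables hold the transcripts that the authors listed as changed, 1447 at 3 weeks and 5571 at 8 weeks, and every count of calls given here is over those lists and not over the genome. The lists were chosen on the same libraries that are tested here, so the calls are not independent evidence of a change. Levels are CPM, counts scaled to the library totals, given as mean ± SD with n = 3, and log2 changes carry ± their approximate standard error. The labels do not say whether the replicates were separate plants, so the p-values measure the spread between these samples, which may be technical.

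The first comparison asked which transcripts differed between HT and NT at 3 weeks. Of the calls, 11 of 12 small heat shock proteins, chaperones that hold unfolding proteins, rose, and 16 of 17 glutaredoxins, small redox enzymes, fell. A chloroplastic small heat shock protein (PGSC0003DMG400003219) rose from 0.716 ± 0.0603 to 127 ± 42.0 CPM, a log2 change of 7.47 ± 0.37 (edgeR quasi-likelihood test, adjusted p = 6.9e-05). A glutaredoxin family protein (PGSC0003DMG400030784) fell from 17.5 ± 1.40 to 0.204 ± 0.0994 CPM, a log2 change of -6.42 ± 0.47 (adjusted p = 0.00016). All 5 called chlorophyll a/b binding proteins, which carry the antenna pigments of the photosystems, and 11 of 12 called ribosomal proteins were lower at HT. Single sesquiterpene synthases and non-specific lipid-transfer protein 1 rose.

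Of the small heat shock protein list, all 12 listed members were called at 3 weeks, 11 higher and 1 lower. With DESeq2 size factors it had 7 and 1, where 23.4% of all calls were higher. The list did not pass the direction test in the main fit (Fisher's exact test, adjusted p = 0.12). A second small heat shock protein (PGSC0003DMG400011977) rose from 2.97 ± 0.273 to 48.4 ± 10.8 CPM, a log2 change of 4.02 ± 0.29. The list of large chaperones and co-chaperones went both ways, with 5 higher and 5 lower (3 and 5 with DESeq2 size factors). All 5 lower calls were DnaJ proteins, which are co-chaperones, as were 2 of the higher. This kind was formed after the values were seen. In the same list heat shock protein 83 (PGSC0003DMG401028907) had no counts in any NT library and reached 1.57 ± 0.666 CPM at HT, at least 78.1-fold higher. A heat shock cognate 70 kDa protein rose by 2.02 ± 0.27 on the log2 scale, to 94.2 ± 11.3 CPM. Heat stress transcription factors had 2 members higher and 1 lower, too few for the direction test. The largest rise outside these lists was that of coatomer subunit beta-1, part of the coat of transport vesicles, which had no counts at NT and 6.45 ± 1.34 CPM at HT, at least 325-fold higher.

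Reactive oxygen scavenging was the list with the smallest p in the direction test, with 3 members higher and 19 lower (Fisher's exact test against the other calls, adjusted p = 6.3e-05). Glutaredoxins made up most of it: of 18 listed, 16 were called lower and 1 higher, 1 had too few counts for the test, and the median log2 change of the calls was -4.38. The glutaredoxin PGSC0003DMG400010764 changed by -7.53 ± 0.50, from 4.77 ± 1.59 CPM at NT. Ribosomal proteins had 1 member higher, by 3.46 on the log2 scale, and 11 lower (adjusted p = 0.0015). Among the 11 were the chloroplastic 50S ribosomal protein 6, which changed by -1.82 ± 0.17, from 354 ± 27.8 to 99.8 ± 4.87 CPM, and 60S ribosomal protein L36, which changed by -1.91 ± 0.27. The cell wall list had 7 members higher and 17 lower (adjusted p = 0.0069). In it an expansin, a wall-loosening protein, changed by -2.65 ± 0.66, and an arabinogalactan protein rose by 3.69 ± 0.47. With DESeq2 size factors, which centre the listed transcripts on no change, none of these lists passed the direction test (adjusted p = 0.55, 0.55 and 0.14 for scavenging, ribosomal and cell wall). The majority of each stayed lower, as 507 of all 662 calls were lower with these factors.

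The light harvesting list held members of both directions at 3 weeks, set out here by kinds formed after the values were seen and not tested as kinds. All 5 listed chlorophyll a/b binding proteins fell, by log2 changes from -1.59 to -2.10, and all 3 photosystem II proteins of 5 and 10 kDa rose, by 2.45 to 3.61 (3 higher and 5 lower, adjusted p = 0.36 for the list). Pathogenesis-related and defence transcripts had 20 higher and 4 lower (adjusted p = 0.12, and 7 and 5 with DESeq2 size factors), including a PR1 protein (PGSC0003DMG400005111), a marker of pathogen responses, which rose from 1.92 ± 0.402 to 15.7 ± 4.21 CPM. Over that list alone the adjustment gave 23 calls in place of 24. The terpene list had 7 higher and none lower (adjusted p = 0.13, and 2 and 1 with DESeq2 size factors), led by a sesquiterpene synthase (PGSC0003DMG400024440) with no counts at NT and at least 19.7-fold higher at HT. Its log2 change of 7.58 ± 1.28 was 6.96 without HT replicate 3. Non-specific lipid-transfer protein 1, which binds lipids outside the cell, rose from 23.7 ± 0.849 to 181 ± 15.1 CPM in a lipid list with 5 higher and 9 lower (adjusted p = 0.13, and 2 and 10 with DESeq2 size factors). A lipid transfer protein (PGSC0003DMG400017133) changed by -2.70 ± 0.55 (-3.30 without HT replicate 3). Ga20 oxidase, an enzyme of gibberellin synthesis, fell from 18.6 ± 6.57 to 2.28 ± 0.553 CPM, a log2 change of -3.02 ± 0.38.

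The other lists tested at 3 weeks did not pass. Ubiquitin and proteasome had 25 higher and 7 lower (adjusted p = 0.14), phenylpropanoid and anthocyanin 17 and 7 (0.49), ethylene 9 and 3 (0.59) and gibberellin 3 and 2 (1), and with DESeq2 size factors each of these turned to mostly lower, at 2 and 7, 3 and 7, 0 and 3, and 0 and 2. Starch and sucrose had 2 higher and 4 lower (0.32), and 2 and 1 with library totals alone. Large chaperones (0.59), auxin (3 and 5, 0.36), cell cycle (1 and 4, 0.14), and proteinase inhibitors and patatin (5 and 8, 0.16) did not pass either. With DESeq2 size factors the last 3 had 0 and 4, 0 and 4, and 0 and 9. Lists with under 5 calls were not tested: cytokinin and senescence had 2 higher and 1 lower each, and turned to 0 and 1, and 0 and 2, with DESeq2 size factors. The others were jasmonate (3 higher and 1 lower), abscisic acid (3 and 0), water and dehydration (2 and 2), small RNA pathway (0 and 3), Calvin cycle (1 and 0), phytochromes and cryptochromes (1 and 0), FT/TFL1 family (1 and 0) and the circadian clock (0 and 0). With DESeq2 size factors jasmonate had 1 and 1, abscisic acid 1 and 0, water and dehydration 0 and 2, and phytochromes and cryptochromes 0 and 0. The transcript in the FT/TFL1 list was matched by the word self-pruning in its name, which does not make it a member of that family. This self-pruning G-box protein rose by 4.46 ± 0.86 from 0.0134 ± 0.0232 CPM and by 7.39 without NT replicate 1, since it then had no counts at NT. For every list but defence at 3 weeks and the terpene list at 8 weeks, adjustment over the list alone gave as many calls as adjustment over all transcripts tested.

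At 3 weeks 1280 of the 1447 listed transcripts had enough counts to test, and 1248 were called, 772 higher and 476 lower at HT (61.9% higher). With DESeq2 size factors the split was 155 higher and 507 lower (23.4% higher), and adjusting over all 33777 tests of the authors left 283 calls. NT replicate 1 lay over 4-fold below both other NT libraries for 68 listed transcripts and over 4-fold above both for 14. Glutaredoxins, chlorophyll a/b binding and PR1 proteins are families of similar genes whose members may share reads.

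**Figure D1:**
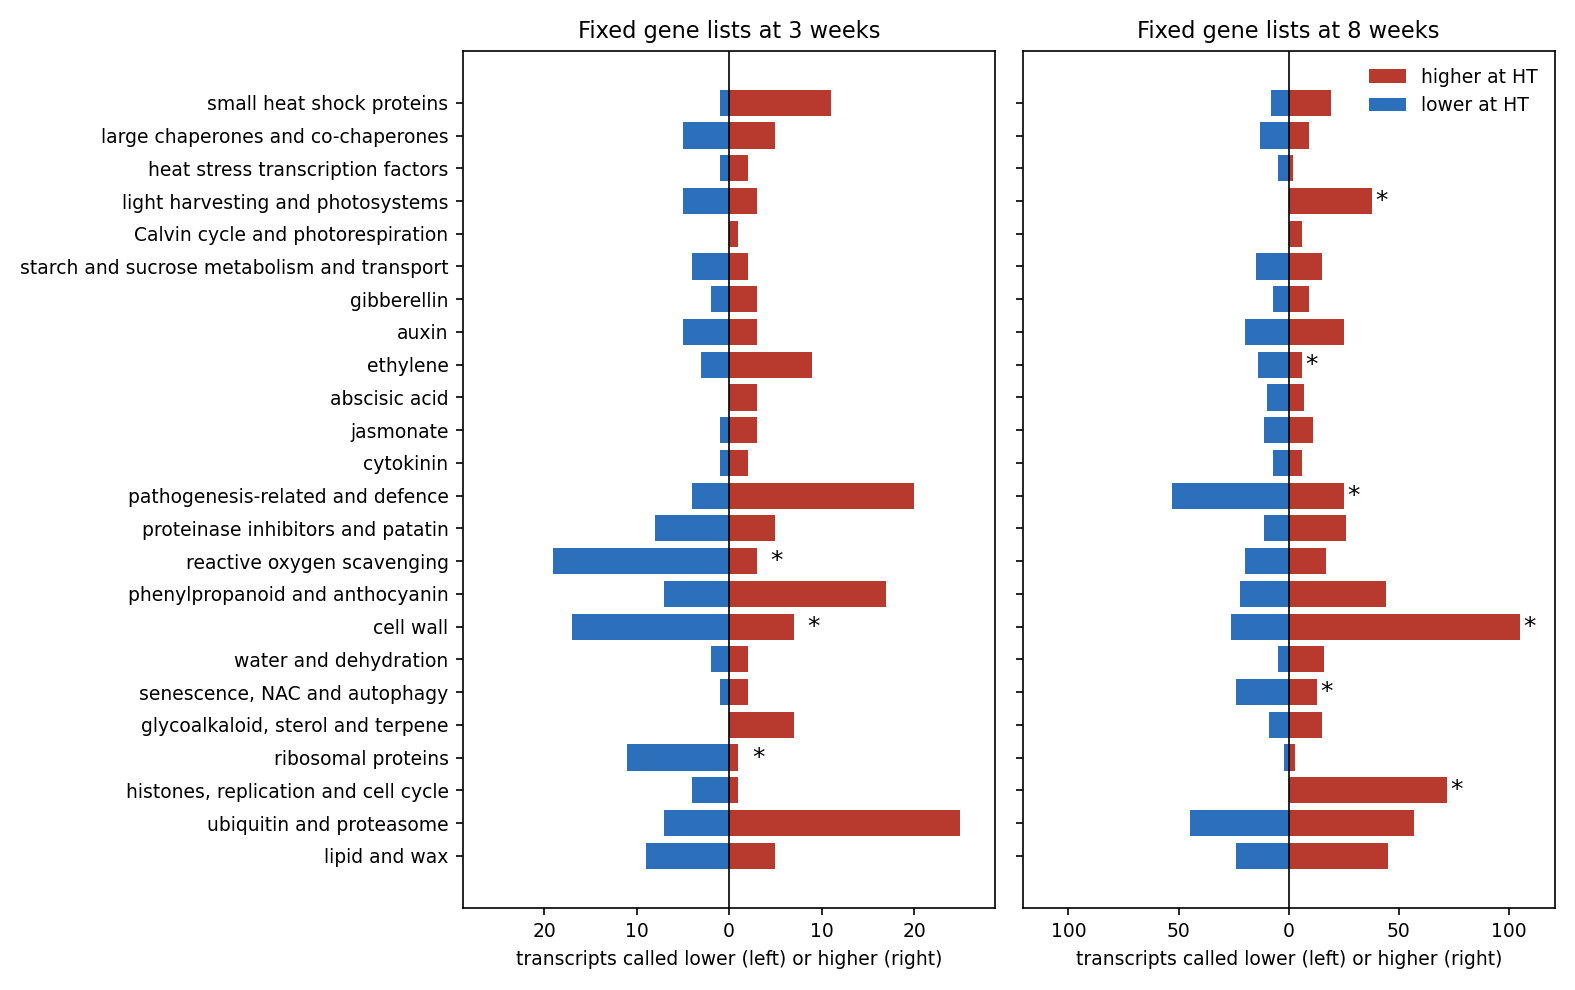
Numbers of transcripts called higher (red, right) or lower (blue, left) at HT in the gene lists with at least 5 calls at one age, at 3 weeks (left panel) and 8 weeks (right panel). An asterisk marks an adjusted p under 0.05 in Fisher's exact test of direction: cell cycle transcripts had 72 higher and 0 lower at 8 weeks, and reactive oxygen scavenging 3 higher and 19 lower at 3 weeks.

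The second comparison asked the same at 8 weeks. Cell cycle and light harvesting transcripts were higher at HT without exception among the calls, most cell wall transcripts were higher, and defence transcripts, among them WRKY factors and PR-1 proteins, were mostly lower. The chloroplastic small heat shock protein named at 3 weeks rose again. Cellulose synthase, the enzyme that makes the main wall polymer, rose from 7.76 ± 1.13 to 786 ± 80.2 CPM (log2 6.66 ± 0.45, adjusted p = 0.00031). The NAC domain protein PGSC0003DMG400001223, of a family of plant transcription factors, fell from 7.68 ± 1.44 to 0.0641 ± 0.0190 CPM (log2 -6.87 ± 0.59, adjusted p = 0.00037).

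All 72 called members of the list of histones, replication and cell cycle were higher at HT (adjusted p = 8.7e-15), with cyclins at 29 higher and 0 lower, kinesins, the motors of the spindle, at 23 and 0, and histones at 17 and 0. Cyclin A2 rose from 1.62 ± 0.504 to 39.0 ± 23.4 CPM, a log2 change of 4.59 ± 0.58 that was 3.98 without HT replicate 1. Library HT replicate 1 stood apart in this list: the median member lay 3.80 on the log2 scale above the NT mean in it, and 1.42 and 1.34 above it in HT replicates 2 and 3. The direction test takes members as independent, though 72 of the 77 listed were highest in HT replicate 1 among the HT libraries. The number of calls was 36 without HT replicate 1, 40 without NT replicate 1 and 42 without NT replicate 2. It was 44 with a replicate block, 30 at an adjusted p under 0.01 and 14 with DESeq2 size factors. In each case all were higher at HT.

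Light harvesting and photosystem transcripts had 38 calls, all higher (adjusted p = 9.0e-08), of which 13 were left, all higher, with DESeq2 size factors (adjusted p = 1.2e-05), and 27 of them were chlorophyll a/b binding proteins. The median member lay 3.15, 1.32 and 1.79 above the NT mean in HT replicates 1, 2 and 3. Chlorophyll a-b binding protein 8 rose from 21.5 ± 4.04 to 296 ± 232 CPM (log2 3.79 ± 0.64, and 2.96 without HT replicate 1). In the Calvin cycle list, with 6 higher and 0 lower (adjusted p = 0.23, and 2 and 0 with DESeq2 size factors), rubisco activase, which reactivates the carbon-fixing enzyme, rose from 9.30 ± 2.77 to 389 ± 184 CPM (log2 5.39 ± 0.58).

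The cell wall list had 105 higher and 26 lower (adjusted p = 1.6e-05, and 62 and 29 with DESeq2 size factors), with the median member 3.20, 1.80 and 2.15 above the NT mean in HT replicates 1, 2 and 3. Pectin methlyesterase inhibitor protein 1 went the other way, from 422 ± 104 to 3.51 ± 2.73 CPM (log2 -6.91 ± 0.74, and -7.75 without HT replicate 3).

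Defence transcripts had 25 higher and 53 lower (adjusted p = 2.0e-06, and 9 and 54 with DESeq2 size factors). Of WRKY factors, regulators of defence genes, 2 were higher and 20 lower, of osmotins 1 and 7, and of PR-1 proteins 0 and 7. Transcription factor WRKY5 changed by -6.13 ± 0.87 from 0.881 ± 0.281 CPM. The senescence list had 13 higher and 24 lower (adjusted p = 0.0092, and 0.16 with DESeq2 size factors). In it the senescence-specific cysteine protease PGSC0003DMG400010207 changed by -8.55 ± 1.62, from 813 ± 700 CPM, where the third NT library held 8.12 CPM against 1157 and 1274 in the others. Cysteine proteinase 3 rose by 8.06 ± 1.02 (7.11 without HT replicate 1). The ethylene list had 6 higher and 14 lower (adjusted p = 0.023), a call lost without any 1 of the NT replicates (0.072, 0.057 and 0.061 without replicates 1, 2 and 3), with DESeq2 size factors (3 and 17, 0.15) and among calls at an adjusted p under 0.01 (5 and 9, 0.22). The ethylene response factor ERF1 rose by 6.30 ± 0.52, to 13.2 ± 1.64 CPM.

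Small heat shock proteins had 19 higher and 8 lower (adjusted p = 0.54, and 14 and 8 with DESeq2 size factors), and their HT medians were alike, 2.71, 2.60 and 2.81 above the NT mean in replicates 1, 2 and 3. The chloroplastic member PGSC0003DMG400003219 rose from 0.723 ± 0.0909 to 135 ± 65.1 CPM (log2 7.54 ± 0.60). Large chaperones had 9 higher and 13 lower (0.23, and 2 and 13 with DESeq2 size factors). DnaJ proteins made up 2 of the higher and 10 of the lower. Heat shock protein 83 (PGSC0003DMG401028907) had no counts at NT and was at least 189-fold higher, and a DnaJ protein, a co-chaperone, fell from 298 ± 99.2 to 21.7 ± 4.28 CPM. Heat stress transcription factors had 2 higher and 5 lower (0.28, and 1 and 5 with them), and both listed HSFB3 transcripts were lower, one (PGSC0003DMG401008167) from 46.6 ± 6.92 to 0.482 ± 0.407 CPM (log2 -6.59 ± 0.74, and -7.52 without HT replicate 3).

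Genes of flowering time and the clock were named whatever their values. The Flowering locus T protein PGSC0003DMG400023365, of the family that carries the signals for flowering and tuber formation, fell from 142 ± 7.86 to 35.3 ± 10.1 CPM (log2 -2.01 ± 0.39, adjusted p = 0.0028). Circadian clock-associated FKF1, a light-sensing F-box protein, changed by -1.97 ± 0.39, from 33.8 ± 3.79 CPM, and CONSTANS, a regulator of the photoperiod response, rose by 1.88 ± 0.42 (0.57 and no longer called with DESeq2 size factors). Protein SELF-PRUNING had no counts at NT and was at least 18.9-fold higher, at 0.342 ± 0.0897 CPM.

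The hormone lists other than ethylene did not pass: auxin (25 higher and 20 lower, adjusted p = 0.54, but 8 and 20 with DESeq2 size factors), gibberellin (9 and 7, 0.87, but 1 and 8 with them), abscisic acid (7 and 10, 0.29, and 2 and 10 with them), jasmonate (11 and 11, 0.52, but 3 and 12 with them) and cytokinin (6 and 7, 0.52, and 2 and 7 with them). The amido synthetase GH3.3, which conjugates auxin, fell from 20.7 ± 4.77 to 0.481 ± 0.127 CPM, and zeatin O-glucosyltransferase, which stores cytokinin in bound form, rose from 0.441 ± 0.241 to 21.9 ± 8.91 CPM. In the sterol and terpene list (15 and 9, adjusted p = 1, but 10 and 10 with them) a C-4 sterol methyl oxidase (PGSC0003DMG400012763) rose from 1.45 ± 0.206 to 128 ± 31.5 CPM. Non-specific lipid-transfer protein 1 rose from 2.63 ± 1.16 to 235 ± 81.4 CPM and a microsomal oleic acid desaturase fell from 68.3 ± 15.5 to 0.797 ± 0.407 CPM in the lipid list (45 and 24, 0.61, and 29 and 25 with them). An ascorbate peroxidase (PGSC0003DMG401001731) rose from 4.39 ± 1.24 to 136 ± 45.2 CPM in the scavenging list (17 and 20, 0.22, but 7 and 21 with DESeq2 size factors).

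The remaining lists had ubiquitin and proteasome at 57 higher and 45 lower (adjusted p = 0.50, but 19 and 46 with DESeq2 size factors), phenylpropanoid and anthocyanin at 44 and 22 (0.52, and 31 and 24 with them), and proteinase inhibitors and patatin at 26 and 11 (0.50, and 15 and 12 with them). Starch and sucrose stood at 15 and 15 (0.48, but 3 and 15 with DESeq2 size factors), water and dehydration at 16 and 5 (0.36, and 7 and 6 with them) and ribosomal proteins at 3 and 2 (1, but 0 and 2 with DESeq2 size factors). Over the sterol and terpene list alone the adjustment gave 25 calls in place of 24. Lists with under 5 calls were the small RNA pathway (4 and 0, but 0 and 0 with DESeq2 size factors), phytochromes and cryptochromes (2 and 0, but 0 and 0 with them), the FT/TFL1 family (1 and 1) and the circadian clock (1 and 1, but 0 and 1 with them).

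At 8 weeks 5176 of the 5571 listed transcripts were tested and 5035 were called, 3068 higher and 1967 lower at HT (60.9% higher). With DESeq2 size factors the split was 1179 higher and 2102 lower (35.9% higher), and adjusting over all 34088 tests of the authors left 2958 calls. HT replicate 1 lay over 4-fold above both other HT libraries for 392 listed transcripts and over 4-fold below both for 206.

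**Figure D2:**
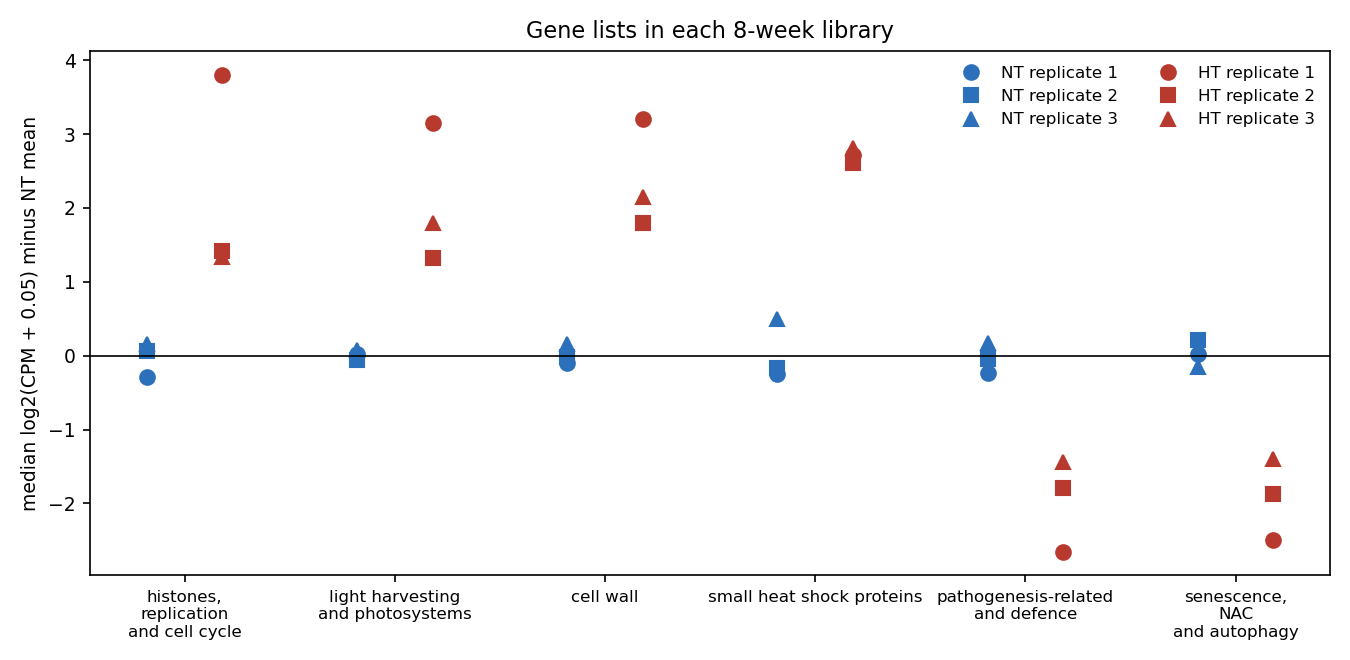
Median over the members of 6 gene lists of log2(CPM + 0.05) minus the mean of the NT libraries, for each 8-week library (blue NT, red HT, the marker shape gives the replicate). HT replicate 1 lies at 3.80 for the cell cycle list, where replicates 2 and 3 lie at 1.42 and 1.34, and the small heat shock medians of the HT libraries lie between 2.60 and 2.81.

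The third comparison asked whether the response to HT differed between the ages. The 8-week plants had also been longer at HT, so plant age and time at HT cannot be told apart. This holds for every comparison between the ages that uses HT libraries. Single chlorophyll a/b binding, PR1 and gibberellin synthesis genes went in opposite directions at the ages, and a small heat shock protein did not. The chlorophyll a/b binding protein PGSC0003DMG400008300 fell at 3 weeks (log2 -1.59 ± 0.11) and rose at 8 weeks (3.40 ± 0.67, and 2.32 without HT replicate 1). The PR1 protein PGSC0003DMG400005111 rose at 3 weeks (3.03 ± 0.34) and fell at 8 weeks (-2.79 ± 0.77, and -3.65 without HT replicate 3). Ga20 oxidase fell by 3.02 at 3 weeks and rose at 8 weeks (2.37 ± 0.60), a difference of 5.40 ± 0.72 (edgeR interaction term, adjusted p = 0.00034). The chloroplastic small heat shock protein PGSC0003DMG400003219 differed by 0.07 ± 0.63 between the ages (adjusted p = 0.99). The antenna and PR1 genes were chosen for mention after their values were seen.

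Both tables listed 580 transcripts, where independent lists would share 239. In the authors' deposited values 270 were higher at both ages, 163 lower at both, 92 higher at 3 weeks and lower at 8 weeks, and 55 the reverse. The 74.7% in the same direction exceeded chance (Fisher's exact test, two-sided, p = 1.0e-31). Of 576 shared transcripts tested, the change at HT differed between the ages for 194. These included 142 of the 146 tested with opposite directions. Both changes of such a transcript were at least 1.5 in the authors' values on the same libraries, so the listing nearly fixed that it would pass. The 194 also held 50 with the same direction and a larger change at 8 weeks, against 2 with a larger change at 3 weeks.

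Among shared defence transcripts, 10 of 15 were higher at 3 weeks and lower at 8 weeks. The difference passed for all 10, as it did for 142 of all 146 tested with opposite directions. Of 7 shared light harvesting transcripts 3 were higher at both ages, and 4 chlorophyll a/b binding proteins were lower at 3 weeks and higher at 8 weeks, each with a difference past the threshold. One of the 4 (PGSC0003DMG400013415), at 48.0 ± 58.4 CPM at HT and 11.2 ± 1.97 CPM at NT at 8 weeks, had a log2 change of 2.10 ± 0.83 that was 0.36 without HT replicate 1 (adjusted p = 0.38), and was not called without NT replicate 1, 2 or 3 either (0.0999, 0.104 and 0.0791). All 11 shared small heat shock transcripts were higher at both ages, with a difference past the threshold for 4. Proteinase inhibitors and patatin had 5 of 11 higher then lower and 4 lower then higher. A sesquiterpene synthase (PGSC0003DMG400010585) changed by 2.96 ± 0.31 at 3 weeks and -3.92 ± 0.67 at 8 weeks.

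**Figure D3:**
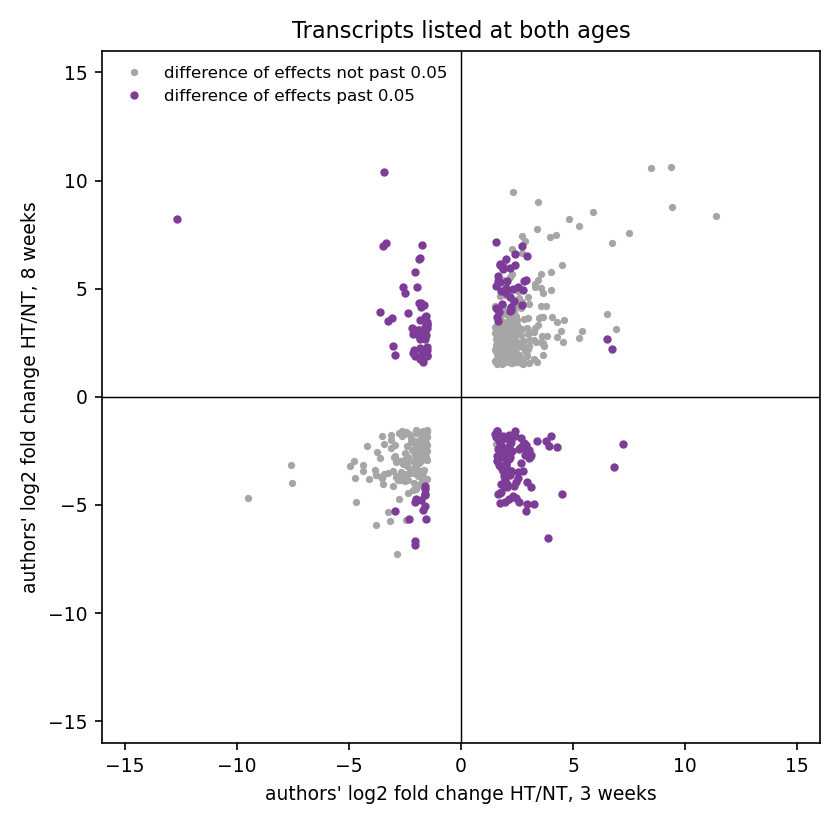
Log2 fold change HT over NT in the authors' deposited table at 3 weeks (x axis) against 8 weeks (y axis) for the 576 tested transcripts listed at both ages. Purple points are the 194 whose change differed between the ages in the interaction test. Most of those in opposite directions, 142 of 146, are among them, which the listing at both ages on the same libraries made likely.

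**Figure D4:**
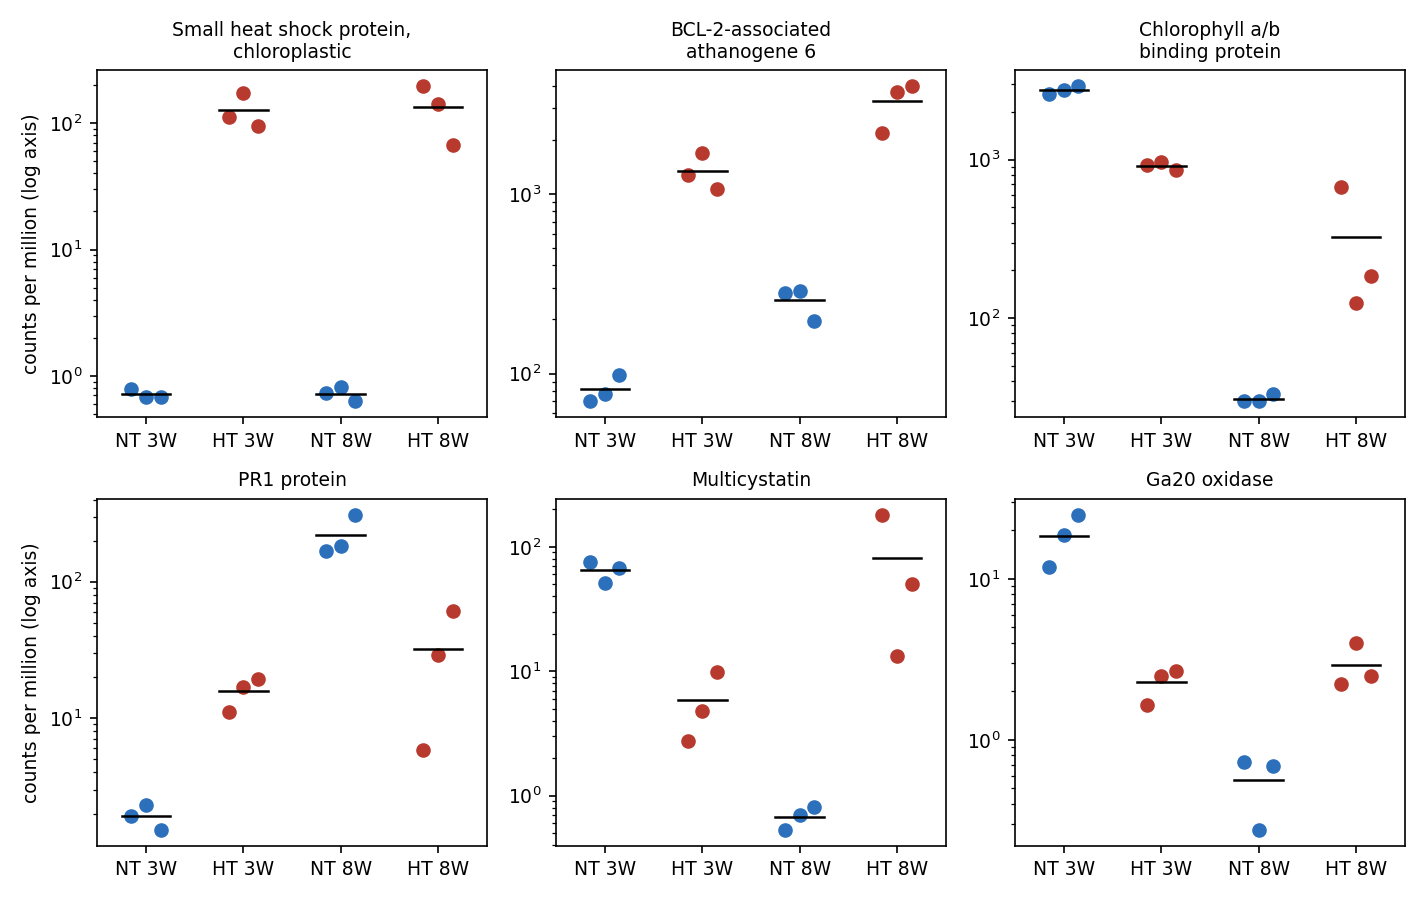
CPM on a log axis in each library (points, 3 per group; blue NT, red HT; lines are means) for 6 genes at 3 and 8 weeks, scaled separately at each age. The small heat shock protein was higher at HT at both ages, while the chlorophyll a/b binding protein, PR1 protein, multicystatin and Ga20 oxidase went in opposite directions; the levels of BCL-2-associated athanogene 6 were 1340 and 3274 CPM at HT at 3 and 8 weeks.

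The last comparison set 8 weeks against 3 weeks within each temperature, over transcripts listed at both ages. At NT the chlorophyll a/b binding protein PGSC0003DMG400008300 was lower at 8 weeks by a log2 change of -6.32 (adjusted p = 2.9e-07), the PR1 protein PGSC0003DMG400005111 higher by 6.99 (adjusted p = 2.2e-05), and Ga20 oxidase lower with -4.89 (adjusted p = 0.000265). At HT the same 3 had log2 differences of -1.64, 0.87 and 0.20, none of which passed (adjusted p = 0.19, 0.49 and 0.72). This does not show that they did not change. Without the 8-week replicate 1 the first was -2.72 (adjusted p = 0.00281) and the second 1.37 (adjusted p = 0.0432), and both then passed. At NT 240 of 450 tested transcripts were called, 169 higher and 71 lower at 8 weeks, with 132 higher and 112 lower under DESeq2 size factors. At HT 37 of 535 were called, 29 higher and 8 lower, with 156 at an unadjusted p under 0.05. Among the 37 were an ascorbate peroxidase (PGSC0003DMG401001731), higher by 1.81, and osmotin OSML15, changed by -4.82 (-5.71 without the 8-week replicate 3). Neither stayed called without the 8-week replicate 2 or 3 or without any 1 of the 3-week replicates (adjusted p from 0.0812 to 0.191 and from 0.0585 to 0.167). The count at HT rested on the libraries used: it was 189 without the 8-week replicate 1, 5 without the 8-week replicate 3, and 0 without the 8-week replicate 2 or without any 1 of the 3-week replicates (127, 109, 104 and 107 at an unadjusted p under 0.05). It was 23 (15 higher and 8 lower) with DESeq2 size factors, and 0 with the replicate number as a block (124 at an unadjusted p under 0.05).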

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

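The interaction test and the overlap of the tables were planned, and the tests of lists between the ages, of left-out causes and of other splits in this part were chosen only after the results were seen.

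Gene lists whose direction at HT differed between 3 and 8 weeks in Fisher's exact test, adjusted over 17 lists, were cell wall (7 higher and 17 lower, then 105 and 26, adjusted p = 3.1e-05), cell cycle (1 and 4, then 72 and 0, adjusted p = 3.1e-05), defence (20 and 4, then 25 and 53, adjusted p = 6.7e-05), light harvesting (3 and 5, then 38 and 0, adjusted p = 0.00017) and reactive oxygen scavenging (3 and 19, then 17 and 20, adjusted p = 0.042, but 3 and 21, then 7 and 21 with DESeq2 size factors). In the scavenging list, called glutaredoxins were 1 higher and 16 lower at 3 weeks, and 2 and 2 at 8 weeks. This 1 family held most of the 3-week calls, so the difference cannot be credited to scavenging as a class. Of single genes named for opposite directions, the 8-week change minus the 3-week change was -8.96 on the log2 scale for osmotin OSML15 (-9.84 without HT 8-week replicate 3, -9.83 without NT 3-week replicate 1, -8.03 without NT 8-week replicate 1). It was 10.37 for multicystatin PGSC0003DMG400005950 (2.59 times smaller as a fold without HT 8-week replicate 1, 1.55 times larger without HT 3-week replicate 3) and -10.32 for TMV-induced protein I (-12.34 without HT 8-week replicate 3, -12.24 without NT 3-week replicate 2). For multicystatin PGSC0003DMG400005921 it was 7.48 (5.94 without HT 8-week replicate 1, 9.71 and 6.89 without HT 3-week replicates 3 and 1, 6.88 without NT 8-week replicate 2). For PGSC0003DMG400045865, a conserved gene of unknown function, the adjusted p of the difference was 0.016 and the call was lost without HT 8-week replicate 1, the library that held the 8-week counts.

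Transcripts that went in opposite directions at the 2 ages numbered 147. An error of scaling is argued against as the whole cause, because it would move all transcripts of an age the same way: of the 142 past the threshold 55 were lower at 3 weeks and higher at 8 weeks and 87 the reverse. At least 132 of the same 142 stayed past the threshold with any 1 library left out, so most of these calls did not rest on 1 library. The 142 were listed at both ages and called on the same libraries, which made it likely that they would stay. The count therefore does not decide whether a single library shaped the pattern. Opposite directions require that the changes with age at NT and at HT differ, so such a difference describes the pattern and is not a cause. The larger change was at NT for 141 of the 147 (95.9%), with a median absolute log2 change of 5.32 against 0.943 at HT. Of the 433 transcripts with the same direction, 64.4% changed more at NT, with medians of 0.888 and 0.607. Whether the larger change at NT reflects the leaf stage of the NT plants was not tested.

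The rise of cell cycle transcripts at 8 weeks was largest in HT replicate 1, and without that library the calls fell from 72 to 36. For the listed members HT replicate 1 is argued against as the only source, since 66 of 77 had HT replicates 2 and 3 above every NT library. The members were listed on all 3 HT libraries, but 61 would reach a log2 change of 1.5 with replicates 2 and 3 at the NT mean, and 50 of these 61 had both above every NT library. The authors' p-value under 0.01 was required on the same libraries too. This favours members with replicates 2 and 3 above NT, so both counts may be too high for cell cycle transcripts at large. An error of scaling is argued against only as the whole cause, since lifting unchanged transcripts by 1.5 would lift all alike and 9.93% of those the authors tested were listed as higher; a smaller error stays open, as DESeq2 size factors left 14 calls and a median log2 change of 1.23 in place of 2.74. More dividing tissue in the HT leaves may underlie the pattern: 72 of the 77 members were highest in HT replicate 1 among the HT libraries, by a median of 2.51 on the log2 scale over the mean of the others, but leaf age per library is not in the labels, so tissue make-up and an effect of temperature within the same tissue cannot be told apart.

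NT replicate 3 at 8 weeks lay over 4-fold below both other NT libraries for 153 transcripts, among them the staygreen protein PGSC0003DMG400010798 at 4.5 CPM against 106 and 164. A mislabelled HT library is argued against by the 19 small heat shock transcripts that rose, whose median lay 3.53% of the way from the other NT libraries to the HT mean. HT RNA mixed into the library would have to make up 75% of it for a 4-fold loss, and the median of all 3068 transcripts that rose lay at 2.07%. Of the 105 called among the 153, 95 were lower at HT (90.5%, against 39.1% of all calls). A 4-fold fall within NT needs NT levels above the floor, which favours transcripts lower at HT, so this share does not decide between causes. A difference in leaf stage among the NT samples may be involved, but leaf stage is not recorded and this cannot be told apart from other differences between the samples.

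The 6 libraries of a comparison can be split in 10 ways, the real one included, too few for a share under 0.05. The real split gave 1248 calls at 3 weeks and 5035 at 8 weeks, and the highest other split 1 and 2. For the change with age the real splits gave 240 calls at NT and 37 at HT, and the highest other split 0 at both. In each of these 4 comparisons 1 of the 10 splits, the real one, gave as many calls. For the interaction 2 of 100 splits gave as many calls as the real one, with 194 in the real split and 292 in the highest other, in which the 3-week labels are nearly exchanged. Because the transcripts were listed on the real split of the libraries, this share leaves chance undecided.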

How the results depend on the processing

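The block and the alternatives fixed in advance are joined here by tests chosen after the data were seen: TMM from the list, library totals alone, adjustment over all tests of the authors, all changes of fit for the lists, and size factors and left-out libraries for the age comparisons. The named results, the named genes and the lists past the threshold, numbered 157, with 1902 values under alternatives. Of these values 1861 kept their direction and their side of the threshold, 41 kept the direction but no longer passed, and 0 reversed. For genes the lack of reversals was nearly fixed in advance, since every listed change was at least 1.5, above any median shift of scaling tried. Genes named as largest changes or list members had the 3 HT libraries on one side of the 3 NT libraries. Leaving out 1 library cannot reverse these. Of the 41 values, 21 came with DESeq2 size factors. These centre listed transcripts on no change, a shift of -1.21 at 3 weeks and -1.28 at 8 weeks, which by construction ends calls of risen transcripts and turned the split of all calls to mostly lower: 662 calls were left at 3 weeks (155 higher), 3281 at 8 weeks (1179 higher) and 23 for age at HT. With them 1 list passed at 3 weeks, which was none of the 3 of the main test. At 8 weeks 7 lists passed, against 6 in the main test. With DESeq2 size factors the ethylene, phenylpropanoid, ubiquitin, gibberellin, cytokinin and senescence lists at 3 weeks and the auxin, gibberellin, ubiquitin and ribosomal lists at 8 weeks had more members lower than higher, the reverse of the main result. None of these lists had passed at that age. Library totals alone shifted the log2 changes by 0.40 and 0.09, and TMM by -0.51 and -0.07. Adjusting over all tests of the authors left 283 and 2958 calls, because the transcripts not listed count as tests. At an adjusted p threshold of 0.01, 5 lists passed at 3 weeks, and the cause was not tested. The 2-fold threshold moved no count, since every listed change exceeds it.

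Within an age, replicate numbers showed no pairing of HT with NT samples: same-numbered libraries correlated at 0.11, 0.081 and -0.038 at 3 weeks and -0.103, 0.043 and -0.008 at 8 weeks. Pairing of same-numbered libraries between the ages was not checked. With the replicate number as a block the calls were 1212 at 3 weeks, 4811 at 8 weeks, 185 for the interaction, 245 for age at NT and 0 for age at HT (124 at an unadjusted p under 0.05). Leaving out 1 library at a time gave 1128 to 1327 calls at 3 weeks, 4459 to 5006 at 8 weeks, 169 to 207 for the interaction, 224 to 248 for age at NT, 0 to 189 for age at HT, 3 lists at 3 weeks and 5 to 6 at 8 weeks. For age at HT the cause was not tested. At this depth and with 3 libraries per group, 71.9% (3 weeks) and 67.1% (8 weeks) of simulated 2-fold changes were recovered. The simulation used a fixed dispersion that was not estimated from these libraries, so the shares for the real data may differ.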

Other observations

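All groups and tests in this part were chosen after the values were seen, by words shared between product names, with 44 words tested at 3 weeks and 202 at 8 weeks (Fisher's exact test against the other calls, adjusted over the words of an age).

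Some groups named by such words leaned to one side. At 8 weeks all 21 listed Hcr2 proteins, receptor-like proteins related to tomato resistance genes, were lower at HT, with a median log2 change of -2.15, and the word hcr2-0a had 0 higher and 9 lower calls (adjusted p = 0.0061). Leucine-rich repeat products had 21 higher and 1 lower (adjusted p = 0.013). Aspartic proteases and aspartic protease inhibitors, the latter part of the proteinase inhibitor list, had 18 higher and 1 lower (adjusted p = 0.026), with a median log2 change of 3.84. Products named for anthocyanin, part of the phenylpropanoid list, had 14 higher and 0 lower (adjusted p = 0.026), and those named for nodulin 4 higher and 13 lower (adjusted p = 0.033). Transporter products went both ways, with 59 higher and 70 lower (adjusted p = 0.012), a share higher below the 60.9% higher of all calls. DnaJ proteins, part of the large chaperone list, had 2 higher and 10 lower (adjusted p = 0.033).

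At 3 weeks products with the word resistance had 16 higher and 0 lower (adjusted p = 0.0044), and the 8 with the word sn-1 were all lower (adjusted p = 0.0044). Products of retroelements had 25 higher and 1 lower at 3 weeks and 21 higher and 5 lower at 8 weeks, and at 8 weeks the word transcriptase had 11 higher and 0 lower (adjusted p = 0.045). BCL-2-associated athanogene 6, a co-chaperone of the BAG family, was among the most abundant transcripts that rose at both ages, from 81.7 ± 14.8 to 1340 ± 309 CPM at 3 weeks (log2 4.04 ± 0.24) and from 255 ± 50.2 to 3274 ± 962 CPM at 8 weeks (3.68 ± 0.46, n = 3, edgeR interaction adjusted p = 0.74). Heat shock factor protein HSF30 rose by 3.05 ± 0.34 and 2.34 ± 0.60 (adjusted p of the difference = 0.47).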
